A study of Homo sapiens with 8 samples.

How the data were processed

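Open chromatin was measured by ATAC-seq, in which a transposase inserts sequencing adapters into accessible DNA, in JJN3 and KMS11, established cell lines grown from human multiple myeloma, a cancer of plasma cells. Per the labels' protocols, the cells were kept in RPMI medium with 5% fetal bovine serum and exposed for 48 h to pomalidomide at 200 nM, to GNE-781 at 40 nM, to the combination or to the solvent DMSO, and nuclei were tagmented with a Nextera kit before PCR amplification and bead purification. Pomalidomide binds cereblon and thereby directs the transcription factors IKZF1 and IKZF3 to degradation, and GNE-781 blocks the bromodomains of the acetyltransferases EP300 and CREBBP. Each of the 8 libraries was placed in its group by its cell line and treatment labels, which gives 1 library for each line and treatment. The design text also speaks of cells that overexpress BATF or eGFP, which are not analysed here.

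The authors deposited 1 table of raw counts for the whole series, whole numbers of reads per peak and library without normalization, over 1 set of 62528 peaks counted in all 8 libraries, a union of MACS2 peaks at q 0.01 per the name of the deposited table, and each peak carries the nearest transcript in the authors' annotation. Per the submitters' processing notes, the tools used upstream were Trim Galore 0.6.4, cutadapt 2.5, Bowtie2 2.3.5.1, SAMtools 1.10, MACS2 2.1.1.20160309 and R 4.1.2, with the genome build GRCh38. How overlapping peaks were joined in this union, whether a read or a fragment was counted, and how duplicates, mitochondrial reads, excluded regions and the offset of the transposase were handled are not given in the sources used here. A peak set made from all libraries favours the deeper ones, and PCR copies counted as reads make counting error look smaller than it is.

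Coordinates are those of the deposited table, in GRCh38. A peak within 1000 bp of the annotated transcript start was called a promoter peak, a peak overlapping the transcript otherwise was called in the gene, and the rest were called intergenic. Of the 62528 peaks, 15930 were promoter peaks (25.5%), 26885 lay in a gene and 19713 were intergenic. The median width was 431 bp, with a range of 161 to 2600 bp. A gene named beside a distal peak is the nearest annotated gene, and its regulation by that peak was not measured. RefSeq gene positions of the same build were used for older gene symbols and for a second assignment of peaks to genes. Motif analysis was planned and needs the genome sequence, which is not used here.

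All computations were made in R 4.3.3. Peaks with a mean CPM of at least 2 over the 8 libraries were kept, which left 62234 and removed 294. Counts were scaled by the trimmed mean of M-values and tested with the quasi-likelihood test of edgeR 4.0.16 in a model with the line as a block and 1 effect per treatment, which leaves 3 residual degrees of freedom. All tests were two-sided, and a peak was called at an adjusted p under 0.05 by the Benjamini-Hochberg method over all 62234 peaks. The same model gave the combination against each single agent and the departure of the combination from the sum of the single-agent changes on the log2 scale. JJN3 was compared with KMS11 over 4 libraries per line, and a call needed a change of at least 2-fold as well. The common biological coefficient of variation was 0.13. Within a line each treatment had 1 library, so within-line differences have no replicate check and are given as log2 ratios with a prior count of 2. The labels do not say that the libraries came from separate cultures, so the p-values measure the spread between these samples, which may be technical. In the treatment tests this spread is the disagreement of the lines about a treatment, taken largely from all peaks together. Each peak's own 3 residual degrees of freedom are weighed against 62.8 prior degrees of freedom borrowed from the other peaks. A peak can therefore be called although the lines disagree there.

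The model was tested on simulated counts for 62082 peaks with the library sizes and means of the treatment comparison, of which 100 were changed 2-fold and 100 were changed 4-fold. For the combination it recovered 24% of the 2-fold and 79% of the 4-fold changes with 4 false calls. In a simulation with no effect, over 62078 peaks, it made 0 calls. For the line comparison, over 62048 simulated peaks, it recovered 62% and 99% with 10 false calls. These were scored by the adjusted p alone, without the 2-fold change that line calls also needed. The recovery of 2-fold changes under the full rule was not measured. All simulated peaks had the same dispersion of 0.017. False calls and recovery where the spread differs between peaks were therefore not measured.

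Summed counts per gene, over all peaks nearest to it, were tested the same way for 25092 gene entries. They were read in 15 gene lists with 377 genes, of which 294 had a peak and 4 were matched by an older symbol: myeloma regulators, plasma cell surface and secretory genes, interferon response, AP-1 and BATF family, ETS family, IKAROS family with cereblon and p300/BET regulators, B cell identity, NF-kB response, apoptosis regulators, cell cycle and cytosolic ribosomal proteins, with markers of T and NK cells, myeloid cells, erythroid cells and megakaryocytes, and stromal, endothelial and epithelial cells. Each list was tested with camera of limma 3.58.1, once with a preset correlation between genes of 0.01 and once with an estimated correlation, and p was adjusted over the 15 lists of a treatment in a family of 45 tests. A list's median within a line was ranked among 10000 random lists of equal size matched on mean signal. Distal peaks closer than 10 kb were joined into clusters, and the 5% with the highest mean signal were set against the others. A distal peak without such a neighbour formed a cluster of 1 peak.

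Named peaks followed a rule. For each treatment these were the 10 largest mean rises and the 10 largest mean falls among called peaks with the same direction in both lines, 1 per gene symbol, filled where fewer passed by peaks that did not pass and were at least 2-fold changed the same way in both lines. For the lines the rule took the 10 largest differences each way, and for the departure from the sum the 5 largest each way. Fixed besides these were 18 regulators and drug targets and, from each list, up to 2 genes with the largest rise and 2 with the largest fall in the combination. The groups, tests, lists, naming rule and most alternatives were chosen before the data were examined. The alternatives were other scalings (DESeq2 size factors, quantile, cyclic loess), the Wald test of DESeq2 1.42.0, other filters, a robust fit, no line block, only the libraries compared, each library left out in turn, and other thresholds for regions, clusters and lists. Chosen after seeing the data were library totals as scaling, thinning of all libraries to equal totals, the RefSeq assignment with 10 kb flanks, a correction of the line comparison by 10 Mb windows, and a model with effects specific to each line, in which the combination is the sum of the single-agent log2 changes.

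Ratios against groups with 1 to 3 counts are given with a 95% interval, and ratios against 0 counts as a lower bound from a floor of 3 counts over the group. Intervals and floors cover counting error only.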

Results

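Accessible chromatin was profiled in 2 myeloma lines, JJN3 and KMS11, after 48 h of DMSO, pomalidomide at 200 nM, GNE-781 at 40 nM or the combination, with 1 library for each line and treatment. The design asks how a cereblon-binding drug and an EP300 inhibitor change chromatin accessibility alone and together. The JJN3 libraries held 1366628 counts under DMSO, 3218581 under pomalidomide, 1582277 under GNE-781 and 2060036 under the combination. The KMS11 libraries held 3786690, 4586400, 2981408 and 5435673 counts in the same order. The median peak had 12 counts in the JJN3 DMSO library and 34 in the KMS11 DMSO library, and 788 peaks had 0 counts in the former against 14 in the latter. Promoter peaks held 47.5% to 50.9% of the counts of a library. Values below are log2 changes ± SE from the model over all 8 libraries, with the log2 ratio of each line where given, and adjusted p is that of edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment unless another test is named.

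Under pomalidomide, single peaks rose near NFKBIA and in TNIP1 and TNFAIP3, which restrain NF-kB signalling, and in the interferon pathway gene USP18, and single peaks fell near the cyclin gene CCND1 and in the mTOR inhibitor gene DEPTOR. Of 62234 peaks tested, 638 rose and 142 fell, 1.25% in all, and 758 of these 780 went the same way in both lines. Calling peaks over both lines favours those where the lines agree, so this share is no separate check. At an unadjusted p under 0.05, 4136 were higher and 2820 (40.5%) lower. Among the 10 rises named by rule the lowest adjusted p was that of CTNND1, which encodes p120 catenin of adherens junctions, where a peak at 11:57778256-57779005 rose by 3.14 ± 0.43 (adjusted p = 6.65e-06), or 8.81-fold, with 2.04 in JJN3 and 3.31 in KMS11. An intergenic peak at 11:61297459-61298184, 35182 bp from the start of DDB1, a subunit of the cereblon ubiquitin ligase, rose by 2.98 ± 0.43 (adjusted p = 1.52e-05). An intergenic peak at 11:69578148-69578584, 62503 bp from CCND1, a driver of the G1 phase, fell by 2.23 on the log2 scale (SE 0.4, adjusted p = 0.000579), with -1.23 in JJN3 and -2.8 in KMS11.

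The other rises named by rule were intergenic peaks nearest to TLE3, RNU6-72P, RP11-350G13.1 and CCDC91 and peaks in DPY19L1, RP11-507B12.2, COL21A1 and TMEM212, with log2 changes from 2.95 at TMEM212 to 3.89 at TLE3. DMSO counts were few at TLE3, with 2 against 52 under pomalidomide for a ratio of 17.2 (95% counting interval 4.52 to 146), and at DPY19L1, with 3 against 55 for a ratio of 12.1 (3.93 to 60.5). Besides the peak near CCND1, falls named by rule were at RP11-43A1.1 (-2.77 ± 0.49, adjusted p = 0.000366), at the GALNT5 promoter, 2:157256657-157257008 (-2.11 ± 0.39, adjusted p = 0.000632), and at LINC00351, ANTXR2, MBP, RP11-168O22.1, IL21-AS1, SYT1 and MRPS33P3, between -3.1 and -1.86.

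NF-kB response genes were the only list past the threshold under pomalidomide, with a median log2 change of 0.18 over 20 genes (camera adjusted p = 0.00884). With an estimated correlation the adjusted p was 0.438. Its median was 0.28 in JJN3, at percentile 99.7 of matched random lists, and 0.07 in KMS11, at percentile 87.8. Of its 67 peaks 3 rose and 0 fell over all peaks, and 3 passed adjusted over the list alone: near NFKBIA, the inhibitor of NF-kB (1.9 ± 0.4, adjusted p = 0.00375), in TNIP1 (1.26 ± 0.3, adjusted p = 0.0137) and in TNFAIP3, the deubiquitinase A20 (1.43 ± 0.36, adjusted p = 0.0227). The list did not pass with promoter peaks only (adjusted p = 0.0677) or distal peaks only (adjusted p = 0.341), and its 5 alternatives ranged from 0.0113 with the RefSeq assignment to 0.341, all at 0.393 or more with an estimated correlation.

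Interferon response genes had a median of 0.16 over 32 genes (camera adjusted p = 0.0517, 0.438 with an estimated correlation). Of their 66 peaks 2 rose and 1 fell, with 5 adjusted over the list alone. A peak in USP18, a brake on interferon signalling (1.21 ± 0.29, adjusted p = 0.0151), rose, and a peak 17091 bp from SAMD9L fell (-1.61 ± 0.36, adjusted p = 0.00861). The list passed with peaks within 50 kb of the start (adjusted p = 0.0427), under cyclic loess (0.0432) and with the RefSeq assignment (0.0147), and its highest alternative was 0.833 with distal peaks only. With an estimated correlation these 3 adjusted p were 0.448, 0.393 and 0.586. Myeloma regulators had 1 peak higher, in MEF2C (2.16 ± 0.45, adjusted p = 0.00382), and 2 lower, near CCND1 and in DEPTOR (-1.33 ± 0.35, adjusted p = 0.0355, with -0.52 in JJN3 and -1.43 in KMS11), out of 138, with 4 adjusted over the list alone. Peaks in ETV7 and ETS1 of the ETS family and near PMAIP1, which encodes the apoptosis protein NOXA (1.14 ± 0.25, adjusted p = 0.00556), also rose. Single peaks of other lists rose in the integrin gene ITGAM and, mainly through KMS11, in BANK1, a B cell adaptor gene (0.11 in JJN3 and 2.08 in KMS11), CDK6 (0.36 and 1.72) and the endothelial receptor gene KDR (-0.37 and 1.7). Marker lists of other cell types also stood above 0: 0.24 for stromal markers (0.14 in JJN3 and 0.39 in KMS11, percentile 100; camera adjusted p = 0.0542, 0.515 with an estimated correlation) and 0.12 with a mean of 0.31 for myeloid markers (0.49 in JJN3, percentile 99.7, and 0.2 in KMS11; 0.0651 and 0.439). The AP-1 list had a camera adjusted p of 0.0542 and the plasma cell list 0.104. The other 9 lists lay between 0.104 and 0.928. For the IKAROS list the median of -0.02 stood against a mean of 0.06 and direction up, and for cell cycle genes the median was -0.03 and the mean 0, direction down.

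These calls rested mainly on KMS11: without its DMSO library 68 peaks were called and without its pomalidomide library 64, where the lone remaining sample is assumed to vary like the others, and DESeq2's Wald test called 72 peaks. Of the 20 peaks named by rule RP11-43A1.1 alone kept its call with any library left out (highest adjusted p = 0.029), while 17 lost it without KMS11 DMSO, 17 without KMS11 pomalidomide, 6 without JJN3 pomalidomide and 2 without JJN3 DMSO. Of the 17 called list peaks 16, 16, 5 and 7 lost it without these and 3 and 2 without the combination libraries of KMS11 and JJN3, with KDR at -0.12 and CDK6 at -0.01 without KMS11 pomalidomide.

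**Figure D1:**
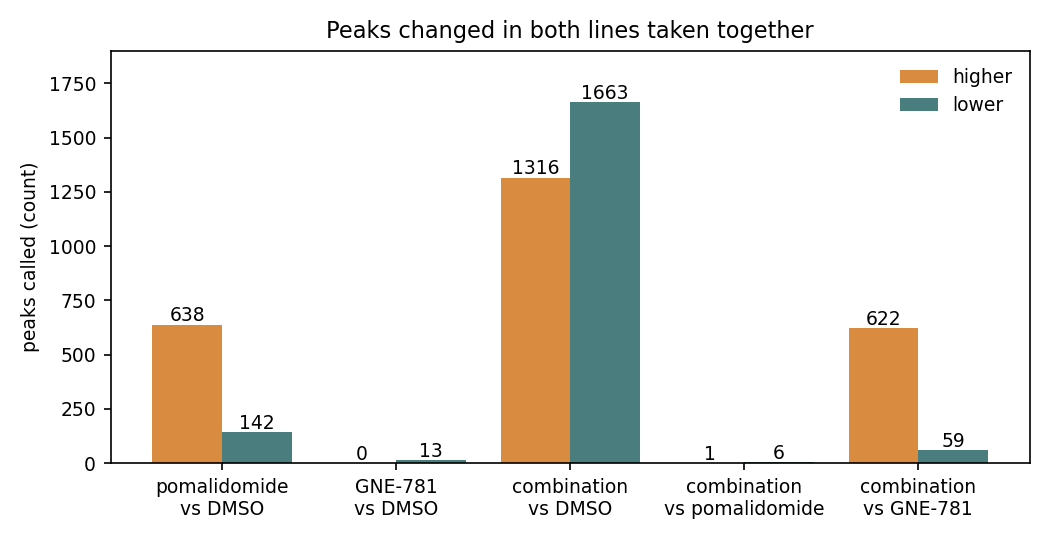
Number of peaks called higher and lower (adjusted p under 0.05) among 62234 tested, for each treatment against DMSO and for the combination against each single agent. Pomalidomide has 638 higher and 142 lower peaks, GNE-781 has 0 and 13, and the combination has 1316 and 1663.

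Under GNE-781, 13 peaks fell and 0 rose in the model over both lines. They included a peak in GALNTL6, a glycosyltransferase-like gene, at 4:172985536-172986636 (-1.5 ± 0.24, adjusted p = 0.00331), a peak in the antisense transcript CDKN2B-AS1 beside the cell cycle inhibitor CDKN2B, at 9:22105022-22105466 (-1.76 ± 0.34, adjusted p = 0.0279), and the promoter peak of XRCC5, which encodes the Ku80 protein of DNA end joining, at 2:216113564-216113946 (-1.67 ± 0.33, adjusted p = 0.0295). At XRCC5 the log2 ratios were -1.53 in JJN3 and -1.67 in KMS11, and at GALNTL6 -0.81 and -1.85. The other named falls were at AC007319.1, COX5BP8, U1, C8orf46, KB-1683C8.1, KANK1 and Y_RNA, from -1.93 to -1.53. At an unadjusted p under 0.05, 4096 peaks passed against 3112 by chance, and 2601 of them (63.5%) were lower. DESeq2's Wald test called 0 peaks, with 1277 at an unadjusted p under 0.05.

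No rise under GNE-781 passed in this model. The model with effects specific to each line, chosen after the data were seen and in which the drugs add, called 26 higher and 81 lower in JJN3 and 138 higher and 841 lower in KMS11, with 2 residual degrees of freedom. The KMS11 libraries were deeper, so these counts do not compare the size of the responses. The fill-in names had log2 changes of 2.55 ± 0.73 at CBX1, a heterochromatin protein gene (adjusted p = 0.305), 2.45 ± 0.62 at a peak inside MAF annotated as RP11-679B19.2 (adjusted p = 0.194) and 2.52 ± 0.58 at LINC01204 (adjusted p = 0.101), and lay between 1.7 and 3.15 at ITCH, IRX2, RP11-415C15.1, ARHGAP24, UPF2, TSPAN8 and LINC01335. At LINC01335 16 counts stood against 2 (ratio 9.03, 95% counting interval 2.12 to 81). None of the 15 lists passed. Cytosolic ribosomal protein genes had the highest median, 0.17 over 31 genes (camera adjusted p = 0.0793, 0.752 with an estimated correlation), and no list had a called peak. Median, mean and test differed in sign for myeloma regulators (0.02, -0.02, down), the ETS family (0.04, 0.08, down) and T and NK markers (-0.05, 0.09, up). Adjusted over the list alone, 1 peak of myeloma regulators and 1 of interferon response genes were lower and 1 of the IKAROS list was higher.

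Most single libraries moved this short list: without the DMSO, GNE-781 and combination libraries of JJN3 36, 28 and 5 peaks were called, and without the DMSO, pomalidomide, GNE-781 and combination libraries of KMS11 2, 6, 1 and 5. All 10 named falls lost their call without the DMSO or without the GNE-781 library of KMS11, 6 each without JJN3 DMSO, JJN3 combination, KMS11 pomalidomide and KMS11 combination, 7 without JJN3 GNE-781 and 3 without JJN3 pomalidomide. A fit of the compared libraries alone called 49 peaks, 6.12% of them higher, and 7.14% of the 28 without JJN3 GNE-781 were higher.

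With both drugs, chromatin closed at peaks of the plasma cell marker gene SDC1, near CCND1 and at the cell cycle genes E2F1 and CCNE2. It opened at peaks far from the annotated start of IKZF3, at the BATF2 promoter and at a peak in MEF2C. The combination changed 2979 peaks, of which 1316 rose and 1663 fell. Among them 2888 went the same way in both lines, which calling over both lines favours. The 2979 were 4.79% of the peaks tested, the share beside which list counts below stand. Near it were the lists of NF-kB (4.48%), B cell (5%), interferon (6.06%) and plasma cell genes (6.56%). The lists ran from 0% for myeloid markers and ribosomal proteins to 18.2% for erythroid markers. CTNND1 rose most significantly, by 3.9 ± 0.41 (adjusted p = 3.36e-09), or 14.9-fold, with 3.27 in JJN3 and 3.75 in KMS11. The XRCC5 promoter fell by 2.82 on the log2 scale (SE 0.35, adjusted p = 2.17e-07), with -2.96 and -2.42, and the GALNT5 promoter, of a mucin-type glycosyltransferase gene, by 2.7 (SE 0.42, adjusted p = 2.33e-05).

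Rises named by rule besides CTNND1 were at RP11-603B13.1 (3.48 ± 0.43, adjusted p = 2.17e-07) and MESTP4 (3.37 ± 0.57, adjusted p = 7.68e-05), and at peaks with 1 to 3 DMSO counts, whose count ratios were 17.2 at TLE3 (95% counting interval 4.52 to 146), 14.4 at KCNH7 (3.76 to 123), 13.8 at RP11-486M23.2 (3.57 to 117), 14.4 at ARRDC3 (2.32 to 597), 12.7 at LINC01335 (3.28 to 109), 10.5 at RP11-31A23.1 (3.39 to 53) and 11.7 at TRAC (3 to 100). Named falls at few counts were TYW3, with 3 counts against 23 and an 11.2-fold lower ratio (3.37 to 58), and RBM10, with 2 against 14 and 10.2-fold lower (2.34 to 92.3). A peak in the proteasome subunit gene PSMA4 fell by 2.95 on the log2 scale (SE 0.55, adjusted p = 0.00039), and LINC01412, ACVR2A, HSP90AA4P, RP11-719L21.1 and AC114954.1 fell by -3.19 to -2.61.

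The counts of calls fell to 1339 without the combination library of JJN3, to 556 without the DMSO library of KMS11 and to 377 without the combination library of KMS11. The balance of 44.2% higher turned to 50.5% and 59.2% higher without the 2 combination libraries in this order and was 38.1% without KMS11 DMSO. DESeq2 called 394, leaving 852 of the 2979 peaks without an adjusted p. CTNND1 (highest adjusted p = 0.000757), XRCC5 (0.0019), RP11-603B13.1 (0.00675), GALNT5 (0.0445) and MESTP4 (0.0457) kept their calls in edgeR whichever library was left out, while the other 15 of the 20 named peaks did not, of which 9 lost theirs without KMS11 DMSO, 9 without KMS11 combination, 7 without JJN3 combination, 4 without JJN3 DMSO and 1 without KMS11 pomalidomide.

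Among myeloma regulators, 7 of 138 peaks rose and 8 fell under the combination, with 20 adjusted over the list alone. A peak in MEF2C, a B lineage transcription factor, at 5:88785632-88786310 rose by 2.6 ± 0.43 (adjusted p = 6.12e-05), and the peak near CCND1 fell by 2.45 on the log2 scale (SE 0.42, adjusted p = 9.64e-05). Peaks in RUNX3 (1.28) and KLF13 (1.47) rose, a peak in DEPTOR fell, mainly in KMS11 (-1.97 ± 0.38, adjusted p = 0.000687, with -0.28 in JJN3 and -2.38 in KMS11, and an adjusted p of up to 0.801 without KMS11 DMSO). So did peaks in ZBTB20 (-1.79) and near FAM46C (-1.24). At the coactivator gene POU2AF1 1 peak rose (1.65) and 2 fell (-1.17 and -1.08). Summed over its peaks, IKZF3 was the only member to pass (0.64 ± 0.14, adjusted p = 0.00426), with 1.02 in JJN3 and 0.39 in KMS11, and no call without the combination library of JJN3 (adjusted p = 0.216). MEF2C was at 0.59 ± 0.18 (adjusted p = 0.0517), CCND1 at -0.81 ± 0.25 (0.0539) and BHLHA15 at -0.48 ± 0.27 (0.389). The list gave a camera adjusted p of 0.933, direction up, while its median was -0.04 and its mean -0.03.

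Of 61 peaks of plasma cell surface and secretory genes 0 rose and 4 fell, with 6 adjusted over the list alone, and the list's median was -0.19 over 16 genes (camera adjusted p = 0.0613, 0.528 with an estimated correlation). In KMS11 the median was -0.34, at percentile 0 of matched random lists, and in JJN3 -0.07, at percentile 32. At SDC1, which encodes the plasma cell marker CD138, 3 peaks fell: the promoter peak at 2:20224802-20225911 (-0.69 ± 0.2, adjusted p = 0.0253) and 2 peaks inside the gene (-1.38 ± 0.32 and -1.09 ± 0.26). The sum over all 8 peaks nearest to SDC1, of which 5 were not called, fell by 0.66 on the log2 scale (SE 0.14, adjusted p = 0.00223), a call lost without the combination library of KMS11 (adjusted p = 0.134). A peak near FCRL5, an immunoglobulin receptor gene, fell (-1.4), while EDEM1 was at -0.76 ± 0.24 (adjusted p = 0.0647) and DERL3 at 0.02.

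The IKAROS, cereblon and p300/BET list had 4 peaks higher and 3 lower of 49, with 8 adjusted over the list alone (camera adjusted p = 0.195, direction up, with a median of -0.07 and a mean of 0.11). A trio of neighbouring peaks 105914 to 109318 bp from the annotated start of IKZF3, the Aiolos gene whose protein pomalidomide removes, rose by 0.67 ± 0.2, 0.91 ± 0.23 and 1.22 ± 0.33. No other peak nearest to IKZF3 was called. Its promoter peak was at 0.7 ± 0.35 (adjusted p = 0.278), and the rest lay between -0.25 and 1.01. DDB1 rose in sum (0.69 ± 0.2, adjusted p = 0.033) through its intergenic peak (3.01 ± 0.43, adjusted p = 4.64e-06), which lost its call without KMS11 DMSO (adjusted p = 0.198). Peaks in IKZF1 (-1.57 ± 0.49, adjusted p = 0.0446), IKZF2 (-1.4) and the acetyltransferase gene KAT2B (-1.61) fell. CRBN, the cereblon gene, was at -0.18 ± 0.19 in the combination and at -0.43 ± 0.19 under pomalidomide (adjusted p = 0.426).

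In the AP-1 and BATF family 3 of 57 peaks rose and 3 fell, with 6 adjusted over the list alone and a camera adjusted p of 0.345. The promoter peak of BATF2, at 11:64996771-64997232, rose by 1.84 ± 0.35 (adjusted p = 0.000571), or 3.58-fold, with 1.29 in JJN3 and 2.09 in KMS11, and lost its call without the DMSO or the combination library of KMS11 (highest adjusted p = 0.164). Peaks in NFE2L1 (1.21) and BACH1 (1.18) also rose, and peaks near JUN (-1.17) and in ATF3 (-0.98) and BACH2 (-1.14) fell. BATF was at 0.32 ± 0.23 (adjusted p = 0.544), BATF3 at -0.13 ± 0.19 and MAFK at -0.48 ± 0.22 (0.255). In the ETS family 6 of 86 peaks rose and 4 fell, with 13 adjusted over the list alone (camera adjusted p = 0.419): peaks in ETV7 (1.79 ± 0.36, adjusted p = 0.000905), ETV1 (1.72 and 2.4) and ETV6 (1.1) rose, a peak in ELF4 (-0.7) fell, and ETS1 and FLI1 had peaks of both directions. ETV4 was at 0.15 ± 0.21, ERG at 1.17 ± 0.64, SPIC at 0.84 ± 0.62, ETV5 at -0.6 ± 0.29 and FLI1 in sum at -0.44 ± 0.14 (adjusted p = 0.0659).

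Cell cycle genes had 2 peaks higher and 6 lower of 102, with 15 adjusted over the list alone, of which 4 were higher and 11 lower (camera adjusted p = 0.125, 0.528 with an estimated correlation). The promoter peak of E2F1, a transcription factor of S phase genes, at 20:33685126-33686099, fell by 1.22 on the log2 scale (SE 0.24, adjusted p = 0.000844). Peaks in CCNE2, which encodes cyclin E2, fell (-2.28 ± 0.39, adjusted p = 9.82e-05, and -1.17 ± 0.34, the latter with a GNE-781 response that differs between the lines in a model where the drugs add), and the summed change of -0.49 ± 0.15, chosen after its value was seen, passed (adjusted p = 0.0497) but did not under quantile scaling, cyclic loess or the stricter filter, nor without any 1 library other than JJN3 DMSO (highest adjusted p = 0.726). At CDK6, a G1 kinase gene, 3 peaks fell and 1 rose, and a peak in CCND3 rose (0.95). RRM2 was at -0.72 ± 0.23 (adjusted p = 0.0651), E2F8 at -0.66 ± 0.22 (0.0801) and CDKN1A at 0.27 ± 0.16.

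Interferon response genes had 2 of 66 peaks higher and 2 lower, with 4 adjusted over the list alone (camera adjusted p = 0.195). The promoters of the RNA sensor gene RIGI, listed as DDX58 (0.93 ± 0.25, adjusted p = 0.0153), and of PARP9 (0.69 ± 0.22, adjusted p = 0.0468) rose, and peaks at SAMD9L (-2.18 ± 0.39, adjusted p = 0.000183) and the ISG20 promoter (-0.84) fell. In sum RIGI (0.92 ± 0.24) and USP18 (0.73 ± 0.21, adjusted p = 0.0394, chosen after its value was seen) rose, DTX3L was at 0.95 ± 0.46 and IRF7 at 0.27 ± 0.23. Among NF-kB response genes 1 of 67 peaks rose, near NFKBIA (1.42 ± 0.41, adjusted p = 0.0294), and 2 fell, in NFKB1 (-2.14 ± 0.5 and -1.02 ± 0.31), and the list gave a camera adjusted p of 0.154. The second NFKB1 peak had 0.29 in JJN3 and -1.14 in KMS11, and was at 0.32 without the combination library of KMS11. CXCL10 was at 0.65 ± 0.49, RELA at 0.41 ± 0.17 and CD40 at -0.22 ± 0.34. Of 101 peaks of apoptosis regulators 4 rose, in or near BMF (1.04), BIK (1.33), PMAIP1 (0.91) and CASP8 (1.24), all of which promote apoptosis, and 4 fell, in CASP8 (-1.12), BCL2 (-1.36 and -1.14) and BCL2L1 (-1.22 ± 0.3, adjusted p = 0.00764), the last pair being genes of survival proteins. The list's camera adjusted p was 0.851, direction up, with a median of -0.02 and a mean of 0. XIAP was at -0.43 ± 0.19 and BIRC5 at -0.24 ± 0.33. A high-signal cluster of peaks nearest to BCL2 or PHLPP1, at 18:63040593-63057984, rose in sum (0.78 ± 0.18, adjusted p = 0.00576). This cluster is not assigned to BCL2 alone, and no single peak of BCL2 was called higher.

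Lists of other cell types stood beside these changes. T and NK cell markers had 1 peak higher, in CD8B (0.8), and 4 lower, of which 3 were in CD247 (-1.1, -0.98 and -0.9) and 1 at the GNLY promoter (-1.18), out of 35, and CD247 fell in sum (-0.43 ± 0.12, adjusted p = 0.0251) but not under cyclic loess (0.0979). CD7 was at 0.85 ± 0.5 and CD3E at 0.7 ± 0.28. Against the mostly lower called peaks, the list's median over 13 genes was 0.4 and its mean 0.21, direction up. Its median was 0.15 in JJN3 and 0.13 in KMS11. Erythroid and megakaryocyte markers had 0 higher and 2 lower of 11, the HBB promoter (-2.32 ± 0.54) and GP9 (-0.89 ± 0.24), and stromal markers had 2 higher and 0 lower of 56, in ACTA2 (2.32) and PECAM1 (1.25). B cell identity genes had 2 higher, both in BANK1 (2.25, with -0.03 in JJN3 and 2.36 in KMS11, and 2.76, with 2.32 and 2.11), and 1 lower, in BLK (-1.8), of 60. Myeloid markers had 0 of 16 called and cytosolic ribosomal proteins 0 of 50. Camera adjusted p values were 0.224 for T and NK, 0.224 for erythroid, 0.125 for stromal, 0.576 for B cell, 0.154 for myeloid and 0.125 for ribosomal lists. None of the 15 lists passed in the combination, and for the myeloid list the median of -0.01 stood against a mean of 0.24 and direction up.

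Over all list genes, 10 gene sums passed in the combination, and none of the 10 kept its call whichever library was left out: 9 lost it without the combination library of KMS11, 7 without its DMSO library, 7 without the combination library of JJN3, 3 without JJN3 DMSO and 1 each without the other 4 libraries. Of the 73 called list peaks 1 kept its call throughout, the one near SAMD9L (highest adjusted p = 0.022), and 63, 63 and 50 lost it without the KMS11 DMSO, the KMS11 combination and the JJN3 combination library, 32 without JJN3 DMSO, and 8 and 7 without the pomalidomide libraries of KMS11 and JJN3.

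Of the 18 regulators and drug targets fixed for this comparison, IKZF3 alone passed as a sum. POU2AF1 was at -0.36 ± 0.12 (adjusted p = 0.0653). MYC was at -0.1 ± 0.15, IRF4, the myeloma survival factor, at 0.04 ± 0.18, IKZF1 at -0.09 ± 0.16, PRDM1 at -0.16 ± 0.14, XBP1 at 0.19 ± 0.24, CCND2 at 0.2 ± 0.33, MAF at 0.18 ± 0.16, CD38 at -0.19 ± 0.19 and SLAMF7 at -0.06 ± 0.19. EP300 and TNFRSF17 had peaks only by the RefSeq assignment, since the deposited annotation gives their peaks to other transcripts. Within 10 kb of the gene bodies, called peaks in the combination numbered 3 of 10 for IKZF3, 1 of 6 for IKZF1, 2 of 7 for POU2AF1, 1 of 11 for MAF and 1 of 3 for TNFRSF17.

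**Figure D2:**
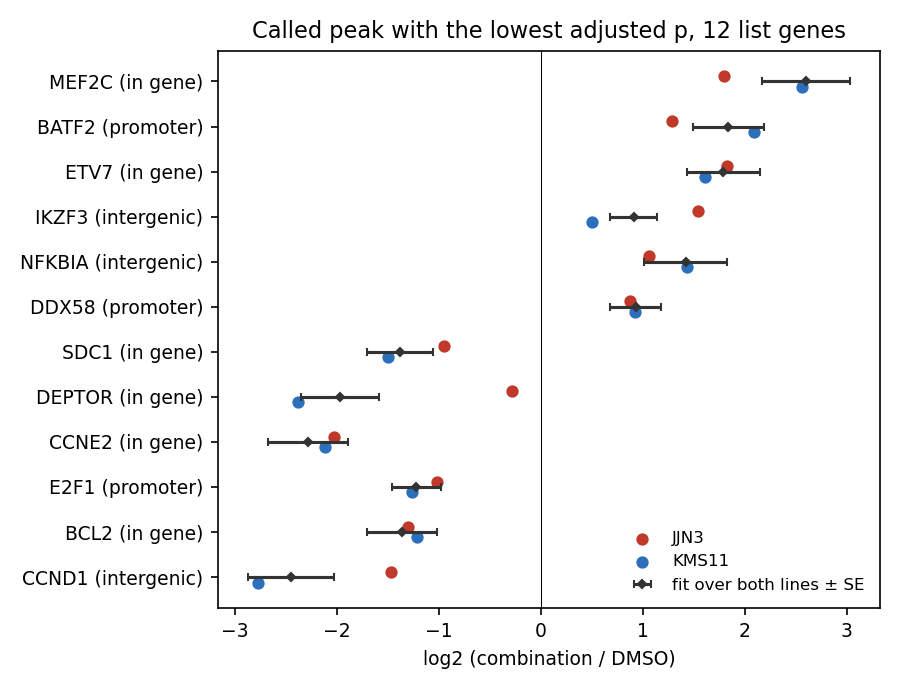
Log2 change under the combination at the called peak with the lowest adjusted p for 12 list genes, with points for JJN3 and KMS11 and the model estimate ± SE. BATF2 (1.84) and MEF2C (2.6) lie above 0 in both lines, and E2F1 (-1.22) and SDC1 (-1.38) below 0 in both.

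The combination was also set against each single agent. Against GNE-781 alone, 622 peaks were higher and 59 lower. Against pomalidomide alone, 1 was higher and 6 were lower, with 4605 at an unadjusted p under 0.05, and DESeq2 called 0. The count against GNE-781 was 353 without the JJN3 combination, 56 without the KMS11 GNE-781 and 91 without the KMS11 combination library, and that against pomalidomide was 0 without the JJN3 combination, the KMS11 pomalidomide or the KMS11 combination library, 28 and 13 without JJN3 DMSO and pomalidomide, 12 without JJN3 GNE-781, and 20 and 15 without KMS11 DMSO and GNE-781.

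No peak passed as departing from the sum of the single-agent log2 changes. How large a departure this test could find was not simulated, so the lack of calls does not show that the drugs add. In edgeR 0 of 62234 passed and 1643 had an unadjusted p under 0.05, against 3112 by chance. DESeq2 called 0, with 216 at an unadjusted p under 0.05, and without KMS11 DMSO edgeR called 1. The largest departures named by rule had an adjusted p of 1: 4.52 ± 1.14 at LINC00351, 3.22 at RP11-56P9.5, 3.17 at RP11-177F15.1, 3.08 at GALNTL6 and 2.92 at CTBP2P4 above the sum, and -3.7 ± 0.97 at DPY19L1, -3.2 at MURC, -3 at DYNC1I2P1, -2.93 at UBL7 and -2.69 at SLC25A20 below it.

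Pomalidomide and combination calls overlapped, but share the DMSO libraries. Of the 638 peaks that rose under pomalidomide 456 (71.5%) rose under the combination, and of 142 that fell 114 (80.3%) fell. Independent lists would share 13.5 and 3.79 peaks, and lists of equal length from counts simulated without any effect, with the same controls, shared 200.6 and 47, at 0 calls. These and the following simulations gave all peaks the same dispersion. For GNE-781 11 of 13 falls were shared, against 0.347 and 6. The DMSO libraries, 1 per line, cannot be split, so part of the excess may come from them. Within lines, the covariance of log2 ratios was 0.368 for pomalidomide and combination in JJN3 (simulated without effect 0.246; r = 0.7 against 0.64) and 0.236 in KMS11 (0.0936; 0.69 against 0.55). It was 0.329 (0.246) and 0.16 (0.094) for GNE-781 and combination, with r = 0.6 against 0.57 in JJN3 and 0.51 against 0.51 in KMS11. For the single agents it was 0.273 (0.246) and 0.107 (0.0938), with r below the simulated value in both lines, 0.57 against 0.61 and 0.38 against 0.49.

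Correlations between lines share no library. Across peaks, which are not independent replicates, the log2 ratios of JJN3 and KMS11 had a Pearson r of 0.17 for pomalidomide, 0.07 for GNE-781 and 0.29 for the combination, with Spearman values of 0.14, 0.07 and 0.27. Crossed pairs gave 0.03 to 0.04 for pomalidomide against GNE-781, 0.19 and 0.21 for pomalidomide against the combination and 0.11 for GNE-781 against the combination. Within JJN3, 7902, 8476 and 10750 peaks changed at least 2-fold under pomalidomide, GNE-781 and the combination, where counting noise alone gave 4711, 6390 and 5163, and within KMS11 4766, 3639 and 6765, where it gave 723, 1312 and 590.

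**Figure D3:**
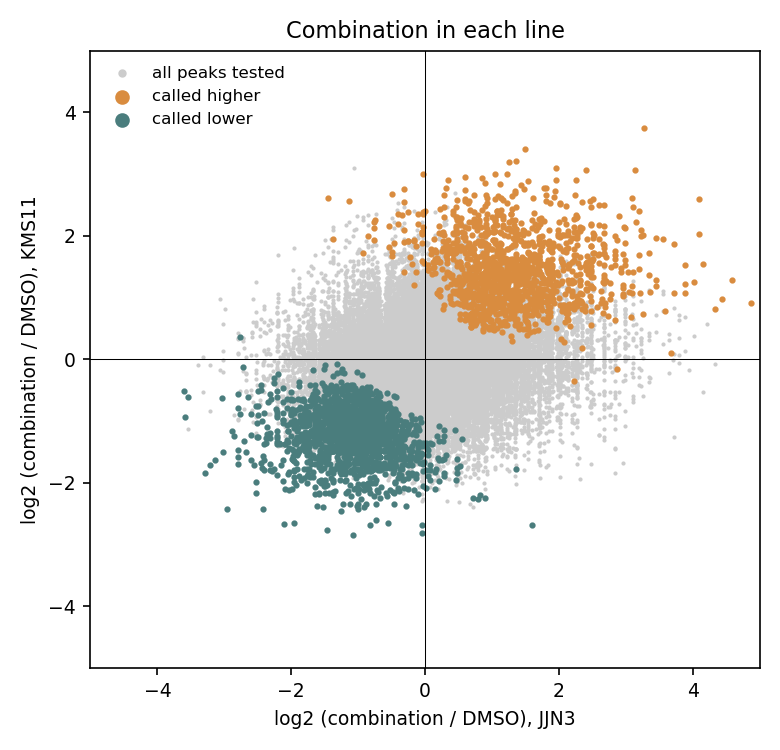
Log2 ratio of the combination to DMSO in JJN3 (horizontal) and KMS11 (vertical) for each tested peak, with peaks called higher in orange and lower in teal. The called peaks, 1316 and 1663, lie mainly in the upper right and lower left quadrants, and 2888 of 2979 go the same way in both lines. Calling over both lines favours such peaks.

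Changes lay mostly outside promoters. Of the combination's calls 9.03% were promoter peaks, against 25.6% of tested peaks, with 128 promoters higher and 141 lower (1.69% of promoters called) against 5.98% of peaks in genes and 5.68% of intergenic peaks. Under pomalidomide 10% of calls were at promoters. Median changes differed little between distal and promoter peaks: distal minus promoter was -0.127 in JJN3 and 0.041 in KMS11 under pomalidomide, -0.034 and -0.039 under GNE-781, and 0.033 and -0.03 under the combination. The series title names super-enhancers. The 1713 distal clusters with the highest signal, of 34247 and some of them single peaks, were compared with the rest as a measure of strongly accessible regions. Their median lay below the rest by -0.055 in JJN3 and -0.073 in KMS11 under GNE-781 and by -0.084 and -0.058 under the combination, and under pomalidomide the differences were 0.09 and 0.006. Averaged over the lines, without a test, the differences of -0.064 for GNE-781 and -0.071 for the combination turned to 0.027 and 0.031 under cyclic loess, which removes trends with signal. As sums, 40 top clusters rose and 90 fell under the combination, against 810 and 904 of the other 32534. Under pomalidomide 33 top clusters rose and 4 fell, against 301 and 70 of the others. These cluster calls were not repeated under cyclic loess, and top clusters have more counts to test. Top clusters at IKZF3 (0.88 ± 0.18, adjusted p = 0.00172) and at GADD45B, a stress response gene (0.93 ± 0.18, adjusted p = 0.00107), rose, and those at XKR6 (-1.18 ± 0.2, adjusted p = 0.000132), CD247, SDC1 and NSMCE2, a SUMO ligase gene (-0.83 ± 0.18, adjusted p = 0.00245), fell. These clusters were chosen after their values were seen.

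**Figure D4:**
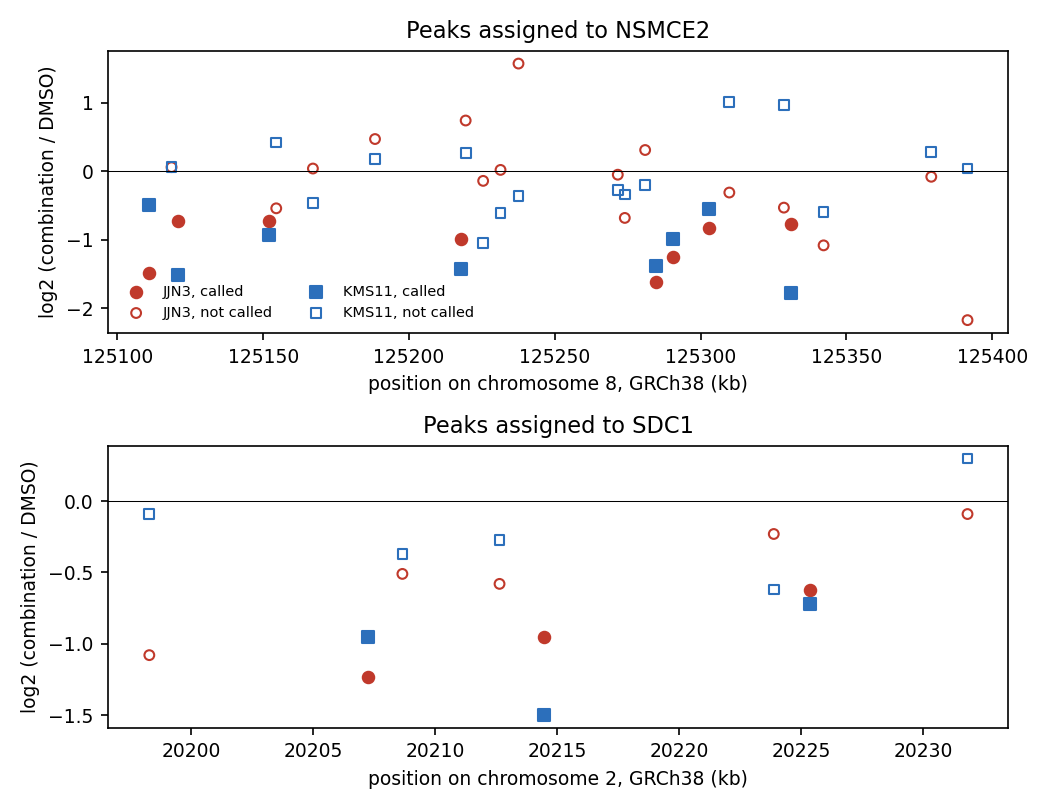
Log2 ratio of the combination to DMSO at each peak nearest to NSMCE2 and SDC1 by position (GRCh38), per line, with called peaks filled. At NSMCE2 8 of 24 peaks are called, all lower, and at SDC1 3 are called, all lower.

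Between the lines, compared over 4 libraries each, 19344 of 62234 peaks differed at least 2-fold, 9952 higher in JJN3 and 9392 higher in KMS11, and leaving out any library gave 17803 to 19514. The immunoglobulin heavy chain locus stood out in KMS11: from 14:105904784 to 106619095, 27 of 34 peaks were nearly absent in JJN3, with 10 counts over its 4 libraries against 5819 in KMS11. Peaks with 0 counts in all JJN3 libraries were at least 94.2-fold higher in KMS11 at IGHVIII-26-1, at least 78.6-fold at IGHVIII-38-1, at least 61.6-fold at IGHM, the mu constant region, at least 59-fold at IGHV4-34, and at least 46.9-, 32.5- and 27.8-fold at IGHV4-55, IGHV3-7 and IGHV3-52. Outside this locus LINC00511 (at least 65-fold), MID1IP1-AS1 (at least 61.9-fold) and ADARB2 (at least 27.3-fold) were among the 10 largest.

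Higher in JJN3 were peaks with 0 counts in KMS11 at the olfactory receptor genes OR4S2, at 11:55657867-55658567 (at least 291-fold), and OR4V1P (at least 75.5-fold), and at UGT2B15, a glucuronosyltransferase gene (at least 26.5-fold). The promoter of GSDMD, which encodes the pyroptosis protein gasdermin D, had 498 counts against 8, a ratio of 127 (95% counting interval 64 to 296). Ratios were 561 (99.9 to 22200) at HCG4B, 85.7 (14.6 to 3460) at CARSP2, with 1 count in KMS11, 85.2 at UPK3B, 60.4 at TSPAN2, 52.6 at HCG4P7 and 49 at KCNH5. Differences also ran over whole chromosome stretches: the median promoter ratio of 10 Mb windows with at least 10 promoter peaks ranged from -1.22 on X to 2.32 on chromosome 1. After correction for it 11741 calls (60.7%) were still called and 329 had the other direction, with peaks in the remaining windows left uncorrected.

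**Figure D5:**
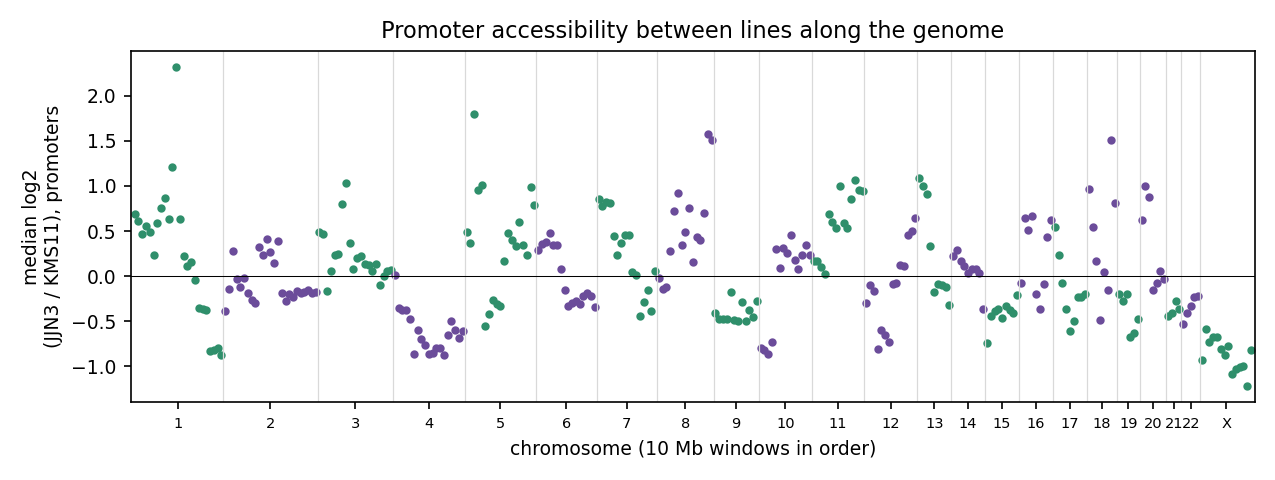
Median log2 ratio of JJN3 to KMS11 over promoter peaks in 297 windows of 10 Mb, by chromosome. The medians range from -1.22 to 2.32, and 99 windows lie beyond 0.5 either way.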

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

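The test of responses that differ between the lines was chosen after the data were seen, and so were thinning, library totals as a scaling and the correction by windows.

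Some peaks answered a drug differently in JJN3 and KMS11, by a test of the difference itself (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). With 1 library per line and treatment, the model takes the combination in each line as the sum of the 2 drugs, which leaves 2 residual degrees of freedom. Its values are fitted effects that also draw on the combination library, not ratios of 2 libraries, and a combination that departs from the sum would enter them. For pomalidomide this model called 760 peaks higher and 344 lower in JJN3 and 2854 higher and 1136 lower in KMS11. Since the KMS11 libraries were deeper, these counts do not compare the size of the responses. Between the lines 42 peaks differed for pomalidomide, 30 with the larger value in KMS11 and 12 in JJN3, and for GNE-781 6 differed, all lower in KMS11. The 6 with the lowest adjusted p for each drug are named here and were chosen after their values were seen. A peak in NPR3, which encodes a natriuretic peptide receptor, had a fitted pomalidomide effect of -0.44 in JJN3 and 2.2 in KMS11 (difference 2.64, adjusted p = 0.00351). For TMEM178B the values were -0.56 and 2.3 (2.86, adjusted p = 0.0265), for a peak in GALNTL6 -1.13 and 0.8 (1.93, adjusted p = 0.0109) and for one near CTD-2351A8.1 -0.53 and 1.29 (1.82, adjusted p = 0.0109). The other direction was seen in F13A1, the coagulation factor XIII gene, with 1.82 in JJN3 and -0.81 in KMS11 (-2.63, adjusted p = 0.0109), and in ANKRD33B, with 0.77 and -0.9 (-1.67, adjusted p = 0.0265).

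Under GNE-781 a peak in CCNE2, the cyclin E2 gene, had fitted effects of 0.09 in JJN3 and -1.72 in KMS11 (difference -1.81, adjusted p = 0.0386), with 31 counts under DMSO and 45 under GNE-781 in JJN3 and 80 and 21 in KMS11. Differences of the same sign were found in ZNF804A (-3.55, adjusted p = 0.0465) and RNF219-AS1 (-3.47, adjusted p = 0.0304) and near AC093901.1 (-2.75, adjusted p = 0.0304), U8 (-2.5, adjusted p = 0.0304) and RP11-317P15.4 (-1.69, adjusted p = 0.0386). In JJN3 counts were few, with 1 under DMSO and 3 under GNE-781 in ZNF804A, 2 and 4 in RNF219-AS1, and 3 and 19 near U8. The median change of distal minus promoter peaks had opposite signs in the lines under pomalidomide, -0.127 in JJN3 and 0.041 in KMS11, and under the combination, 0.033 and -0.03; these differences between lines were not tested.

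Treatment effects shared by the lines were set against every way of matching the KMS11 libraries to the treatments. The real labels gave 2747 peaks called over all treatments, and of the 24 matchings 1, the real one, gave as many. The highest other was 1311, with the DMSO and GNE-781 libraries of KMS11 exchanged, and the next was 1106, with its pomalidomide and combination libraries exchanged. A share of 1 in 24 is the smallest this test can give, and chance matching is argued against only at that level. In both lines the DMSO and GNE-781 libraries were shallower than the pomalidomide and combination libraries. The matchings therefore cannot separate a treatment effect from this shared order of depth.

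Differences between JJN3 and KMS11 ran over long stretches of chromosomes, which raises copy number as a candidate explanation. Of the 35 splits of the libraries into 4 and 4, 1, the real one, gave as many calls as 19344, and the highest other gave 0. Every other split mixes the lines within its groups, which puts the line difference into the residual spread. That outcome was thus largely fixed in advance, and no conclusion about chance is drawn from it. Peaks were corrected by the median promoter ratio of their 10 Mb window where it held at least 10 promoter peaks, and left as they were elsewhere. After this 11741 of the 19344 calls (60.7%) were still called and 329 had the other direction, while 14311 peaks passed in all, new ones included. Copy number of whole windows is thus argued against for the 11741 as a set, except for any in uncorrected windows. It stays open for the others. Also open are steps shorter than a window, among others at the immunoglobulin heavy chain locus, where 10 counts in JJN3 stood against 5819 in KMS11, and at the stretch from 11:55657867 to 55674319, with 539 counts in JJN3 and 0 in KMS11. Separate origins of the lines are the biological explanation the design names, and it was not tested apart from these.

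Pomalidomide calls were mostly higher, 81.8% of 780, which scaling or the thin JJN3 DMSO library could produce. Over 4 other scalings the lowest share of higher peaks was 78.1%, and after thinning all libraries to equal totals 83.4% of the 217 called peaks were higher. Both values lie above an even split and argue against scaling and unequal counts per peak as the whole cause. The thinned counts still used peaks found in the full libraries, and pomalidomide was deeper than DMSO in both lines. Thinning cannot undo such a choice of peaks, so depth stays open by that route. Without the JJN3 DMSO library the share was 69.7% of 610, the lowest with any library left out, without KMS11 DMSO it was 70.6% of 68, and among all peaks at an unadjusted p under 0.05 2820 (40.5%) were lower. A shift of 1 DMSO library of its own stays open, since each line has 1, and a drug effect that opens chromatin at selected sites remains a hypothesis.

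Combination calls were mostly distal, with 1.69% of promoters and 5.85% of distal peaks called, and promoter peaks differ from distal peaks in signal and width. Drawn to match promoters in signal, 9.84% of distal peaks were called, and drawn to match in width 9.62%, with an SD of 0.24 over 100 draws for each. Signal and width per peak therefore do not account for the excess and, where matched, widen it. A response of enhancers more than promoters to the 2 drugs may underlie this, as a hypothesis made and tested on the same data.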

How the results depend on the processing

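Library totals, thinning to equal totals, the RefSeq assignment and the window correction were chosen after the data were seen. DESeq2's Wald test called 72 peaks for pomalidomide, 0 for GNE-781, 394 for the combination, 0 for the combination against pomalidomide and 92 against GNE-781. It gave no adjusted p to 27751, 0, 26545, 0 and 30164 peaks in the same order, among them 204 of the 780 pomalidomide calls and 852 of the 2979 combination calls, so most calls were lost at peaks that had one, and the cause was not tested. Without the cell line block each of these 5 counts was 0, since differences between the lines then stay in the residual spread. Thinned to equal totals they were 217, 5, 1171, 0 and 290, with fewer counts to test. For GNE-781 quantile scaling gave 8, cyclic loess 7, library totals 5, the filter at a mean CPM of 5 gave 7 and the compared libraries alone 49, where the cause was not tested.

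Leaving out each library in turn gave 64 to 1019 calls for pomalidomide, 1 to 36 for GNE-781, 377 to 3286 for the combination, 0 to 28 for it against pomalidomide, 56 to 912 against GNE-781, 0 to 1 for the departure from the sum, and 17803 to 19514 between the lines, with the lone sample left assumed to vary like the others. The extremes of KDR were -0.12 and 1.69, of the CDK6 peak -0.01 and 1.92, both under pomalidomide, and of the NFKB1 peak -1.16 and 0.32 in the combination. Of the 2979 combination calls 2875 remained with DESeq2 size factors, 2860 with quantile scaling, 2614 with cyclic loess, 2626 with library totals, 2966 without a filter and 2971 in a robust fit, and none reversed under these alternatives, while 35 reversed without KMS11 DMSO, 19 without the KMS11 combination and 1 without JJN3 DMSO. In the line comparison the counts kept within 1.5 times of 19344 under all alternatives run, with 14311 after the window correction.

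In the order pomalidomide, GNE-781, combination, peaks changed 1.5-fold numbered 20027, 20794 and 24262 in JJN3 and 14749, 13941 and 17854 in KMS11, and 3-fold 1931, 2372 and 3230, and 887, 394 and 1372. With the stricter filter, which tests fewer peaks, 2-fold counts were 4792, 5009 and 7017, and 2787, 2123 and 4200, and a prior count of 4 gave 2366 for GNE-781 in KMS11. Averaged over the lines, distal minus promoter was -0.043, -0.036 and 0.002, with -0.024, -0.052 and -0.052 under cyclic loess and -0.027 for GNE-781 with promoters of 3 kb. Top clusters minus the rest, averaged in the same way, was 0.048, -0.064 and -0.071. Cyclic loess gave 0, 0.027 and 0.031, and the highest 1% gave -0.102 for GNE-781 and -0.115 for the combination. Correlations between lines of 0.165, 0.071 and 0.287 were 0.249, 0.093 and 0.399 over the 15559 peaks with the highest signal, and 0.275 for the combination under cyclic loess. Myeloid and stromal lists under pomalidomide passed with peaks within 50 kb of the start (camera adjusted p = 0.0481 for each, 0.537 with an estimated correlation), and their highest alternatives were 0.349 and 0.621. Motif alternatives, pseudocounts for normalized values and peak presence were not run.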

Other observations

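The loci of this part were chosen after their values were seen, and the readings between lines were tests whose outcome was stated before they were made.

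A few genes carried many called peaks of 1 direction under the combination, while most genes with 4 or more called peaks had both, among them RUNX2 and SETBP1 with 2 higher and 2 lower each. PTPRN2, which encodes a phosphatase-like protein of secretory granules, had 9 of 67 peaks lower from 7:157696938 to 158577549, with a median log2 change of -0.93 over the called peaks, -1.19 in JJN3 and -0.65 in KMS11. TTC34 had 9 of 16 lower (median -0.75, with -1.31 in JJN3 and -0.23 in KMS11), and NSMCE2, of the SMC5/6 complex, had 8 of 24 lower (-1.12, with -0.91 and -1.19). At XKR6 4 of 17 peaks were lower (-1.37). NFIA, a transcription factor gene, had 3 peaks higher and 1 lower of 25, and INPP4B, a lipid phosphatase gene, 3 higher and 1 lower of 17, with medians over the called peaks of 1.39 and 1.2.

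Summed over all peaks of a gene, 388 gene entries were higher and 503 lower under the combination, 117 and 35 under pomalidomide and 0 and 0 under GNE-781, of 25092. A cluster at BHLHE40, a transcriptional repressor gene, was higher with both drugs (0.76). Clusters of only 1 peak each at PRKCA, a kinase gene, and FCRL1, an Fc receptor-like gene of B cells, were lower (-1.1 and -0.93).

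A hypothesis was that peaks lowered by the combination in 1 line are lower under each single agent in the other line, which shares no library with the first. In 4 of 4 readings the median lay outside the central 95% of matched random peaks: -0.196 for pomalidomide and -0.182 for GNE-781 in KMS11 at the 1000 peaks picked in JJN3, and -0.329 and -0.194 in JJN3 at those picked in KMS11. The pomalidomide and GNE-781 readings within a line share that line's DMSO library, so the 4 are not independent. Chance selection of peaks is argued against for all 4, and each agent may thus contribute to the falls in both lines. For peaks raised by the combination, 3 of 4 readings lay outside: 0.331 for pomalidomide in KMS11, and 0.494 for pomalidomide and 0.147 for GNE-781 in JJN3. The fourth, GNE-781 in KMS11, was 0.065 within the random range of -0.023 to 0.068, so chance selection of peaks stays open there. Peaks of 1 library are not independent replicates, and a property that both lines share, such as the sequence or width of a peak, was not tested.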
